A study of Mus musculus with 32 samples.

How the data were processed

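Total RNA was extracted with TRIzol, and biotinylated cRNA made from 4 ug of it was hybridised by the manufacturer's standard protocol to an Affymetrix mouse array of 22690 probe sets. The authors' deposited table of 1 value per probe set and array was used as the starting point. The values are background-subtracted intensities on a linear scale, brought to a common scale between arrays by the authors with software and a method that the sources used here do not give. Image files were not used. No array was identical to another (0 identical pairs), and arrays of the same group correlated at 0.962 to 0.988 (Pearson, across probe sets, which are not independent replicates). The first principal component of a region held 19.5% of the variance in medulla and 17.8% in midbrain.

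Values under 0 were set to 0, 16 was added and the log2 was taken. Quantile normalization then gave all arrays the same distribution. The 64 control probe sets with an AFFX prefix were left out and the other 22626 were tested, with no filter on brightness. Of these, 20380 carried 1 gene symbol (12393 genes), 691 several and 1555 none. Chromosomes and the order of neighbouring genes came from the RefSeq annotation of GRCm38.p6, to which 20351 probe sets were matched by gene identifier. Groups, comparisons, tests, the threshold, gene lists, the rule for naming genes and most alternatives were chosen before the data were examined, and the floor at 0, the order of flooring and normalization, and 3 further alternatives were chosen afterwards.

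For each region a linear model with a mean for each of its 4 groups was fitted to its 16 arrays with limma (lmFit, then eBayes), and comparisons between regions used all 32 arrays and 8 group means. The comparisons were genotype averaged over operation, genotype in sham mice, genotype in CCI mice, CCI in control mice, CCI in KO mice, the genotype by CCI interaction, midbrain against medulla, and the interactions of genotype and of CCI in control mice with region. Every p is from limma's moderated test with both tails, adjusted by Benjamini and Hochberg within a comparison, and an adjusted p under 0.05 counted as past the threshold. The design describes arrays of a group as separate animals. Consecutive array numbers in the sample descriptions place a medulla and a midbrain array with the same animal. Residuals of such arrays correlated at 0.171 on average, and those of other pairs within an animal group at -0.057. The latter value is no baseline: residuals from a group mean sum to 0, so it follows from the former. For KO sham 3 and 4, titles and array numbers disagree, and the residuals correlated at 0.158 when paired by array number and at -0.066 when paired by title. The array code of the descriptions, which may mark a batch, was a lower code for most arrays of replicates 1 and 2 and a higher code for replicates 3 and 4, with a code of its own for control sham 1. Fits within a code therefore held at most 8 arrays of a region.

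Alternatives were median centring in place of quantile normalization, quantile normalization before the floor, a pseudocount of 1 or 64, a filter on the dimmest 33.3% of probe sets, a trended robust variance and array weights. Others were fits to only the groups of a comparison, the array code as a block or fits within it, the title number or the animal as a block, 1 probe set per gene, and the omission of each array in turn, of the arrays that stood apart on the first principal component and of the animals of low Ttr level in the medulla.

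Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on the probe set of highest mean level per gene, and adjusted over the 27 lists of a comparison. Fry and camera with an estimated correlation were the alternatives. Of the listed symbols 4 could not be resolved. The lists were the CCK system (4 genes measured), Toll-like receptor and innate signalling (32), interferon response (24), opioid system (10), neuropeptides (21), monoaminergic neuron genes (19), GABA and glycine transmission (20), glutamate receptors and transporters (17), ion channels studied in pain (27), microglia and macrophage markers (23), astrocyte markers (20), oligodendrocyte and myelin genes (20), pan-neuronal genes (26) and endothelial markers (20). The others were choroid plexus markers (14), meningeal and fibroblast genes (20), red blood cell and granulocyte genes (12), immediate early genes (29), nerve injury and regeneration genes (28), glucocorticoid and stress response genes (22), circadian clock genes (19), heat shock and unfolded protein genes (28), synaptic plasticity kinases and scaffolds (28), midbrain-patterning genes (22), hindbrain Hox and medullary genes (23), oxidative phosphorylation (80) and cytosolic ribosomal proteins (47).

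Genes were named by a fixed rule. Per comparison and direction, up to 10 genes past the threshold (5 for genotype within an operation and for interactions) were ranked by absolute log2 difference, with the probe set of lowest p for each gene and only probe sets with 1 symbol. Where fewer than 5 passed, the genes of smallest p filled up to 5 and are given as not passing. Up to 4 members of smallest p were drawn from each list. Every probe set of Cckbr, and Cck, Cckar and Tlr4 were always included, Tlr4 because published work on these mice names it. Of these genes the text prints those that carry a comparison. Neighbours of Cckbr were the 50 measured genes on each side of it on chromosome 7, compared with all other genes by Fisher's exact test. A gene counted there if any of its probe sets was under the threshold, so genes with several probe sets count more easily.

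In simulated arrays of the same design with independent normal noise, limma recovered 64.2% of changes of log2 0.5, 92.5% of log2 1 and 100% of log2 2 for genotype averaged over operation in the medulla. For CCI in control mice in the medulla it recovered 38.8%, 89.6% and 100%, and for the interaction there 11.9%, 53.7% and 100%. In midbrain the values were 68.7%, 94% and 100% for genotype, and 7.46%, 53.7% and 95.5% for the interaction. Each run changed 67, 67 and 66 probe sets of these sizes at once. With fewer changed probe sets the adjustment within a comparison is stricter, so these rates overstate the recovery of a lone change. A list shifted by log2 0.5 was called in all 9 comparisons, and 0 of 26 other lists were called. With independent noise the simulation cannot show false list calls that come from correlated genes. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.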

Results

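Messenger RNA levels were measured with short-oligonucleotide expression arrays in the midbrain and the medulla of control mice and of mice lacking Cckbr, the cholecystokinin B receptor (here KO mice). Mice of each genotype had either a sham operation or chronic constriction injury (CCI), in which loose ligatures around the sciatic nerve produce a lasting model of neuropathic pain. The combination of genotype, operation and region gave 8 groups of 4 arrays, 32 arrays in all, and the design describes the 4 arrays of a group as coming from 4 separate animals. Each value is a background-subtracted intensity on a linear scale. Array medians lay between 91.1 and 100, and 2.15% of all values were at or below 0. The number of arrays, 4 per group, limits the precision: the median standard error (SE) of a log2 difference was 0.10 for a genotype effect averaged over both operations, 0.14 for a comparison of 2 groups and 0.19 for a genotype by CCI interaction. Fold changes are on the scale of log2(intensity + 16), which understates the change of dim genes.

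The targeted gene itself was compared first. Cckbr, the receptor for cholecystokinin that predominates in the brain, was at background level in every KO group. The brighter of its 2 probe sets read 152 ± 11.9 intensity units (SD, n = 4) in control sham medulla and 171 ± 25.2 in control CCI medulla, against 13.8 ± 7.70 in KO sham medulla and 10.8 ± 2.62 in KO CCI medulla. In midbrain it read 152 ± 21.2 in control sham and 168 ± 8.35 in control CCI mice, against 8.13 ± 6.60 in KO sham and 7.09 ± 1.23 in KO CCI mice. Every KO array lay below every control array in both regions. Where the probes lie relative to the deleted part of the gene is not given in the sources used here. Averaged over both operations Cckbr fell in medulla (log2 difference -2.66, SE 0.11, adjusted p = 6.49e-09) and in midbrain (-2.91, SE 0.11, adjusted p = 1.71e-09). No fold is given, because KO levels were at background and these differences depend on the pseudocount of 16. Array descriptions carry a code that may mark a batch, a lower code for most arrays of replicates 1 and 2 and a higher code for replicates 3 and 4. Within the lower array code the Cckbr difference was -2.78 in medulla (adjusted p = 0.0738) and -3.01 in midbrain (0.505), and within the higher code it was -2.51 (0.0332) and -2.85 (0.00365), each from a fit to at most 8 arrays. The dimmer Cckbr probe set passed in medulla (-1.02, SE 0.17, adjusted p = 0.0387) and not in midbrain (-0.79, SE 0.16, adjusted p = 0.163). Its medulla call was lost in 12 of the 16 fits that left out an array in turn (adjusted p from 0.0646 to 0.122). The 4 arrays whose omission left it in place were KO CCI 2, KO CCI 4, KO sham 1 and KO sham 4. Of 13 other settings 11 lost it, among them the array code as a block, at 0.169 with 3 levels and at 0.0605 with 2, and a pseudocount of 1 (0.610).

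**Figure D1:**
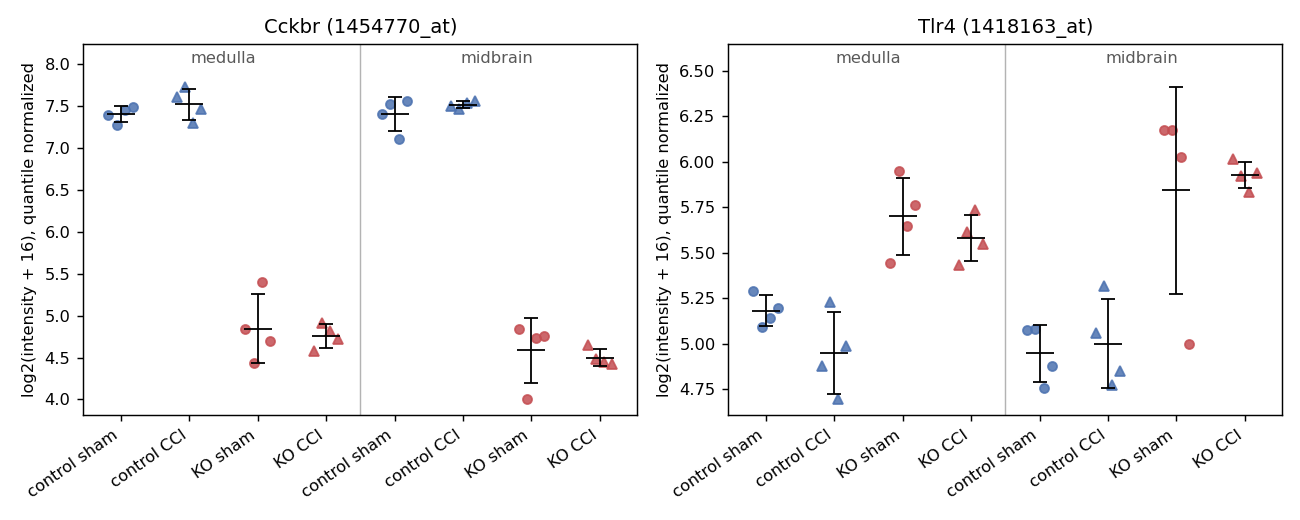
Level of Cckbr (left) and Tlr4 (right) on each array, as log2(intensity + 16) after quantile normalization, in the 8 groups of 4 arrays (circles sham, triangles CCI, blue control, red KO; bar and whiskers, mean ± SD). In Cckbr all KO arrays lie below all control arrays in both regions, and in Tlr4 the array KO sham midbrain 4 lies at 4.998, far below the other KO arrays and near the control midbrain level.

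The genotype effect in the medulla, averaged over sham and CCI mice, asks what else differs in a region that relays descending pain control when Cckbr is missing. Apart from Cckbr, 9 genes passed. Axin1, a scaffold of the beta-catenin destruction complex, rose 2.37-fold on 1 of its probe sets (SE of log2 0.17), from 69.8 ± 6.45 in control sham medulla to 221 ± 129 in KO sham medulla (SD, n = 4). Iqgap1, a scaffold of the actin cytoskeleton, rose 1.91-fold (SE of log2 0.11), from 91.6 ± 20.6 to 223 ± 29.8 in the same groups. Dctn5, a subunit of dynactin, fell 2.36-fold (SE of log2 0.15), from 695 ± 32.4 in control sham medulla to 290 ± 84.1 in KO sham medulla. Myo7a, an unconventional myosin of sensory hair cells, fell 2.05-fold (SE of log2 0.14), and smaller falls were seen in Hdgfl3 (1.68-fold), in Pgap2, which remodels GPI anchors (1.66-fold), and in Spon1, a secreted matrix protein (1.63-fold). Tlr4, the receptor for bacterial lipopolysaccharide, rose 1.49-fold on 1 of its 2 probe sets (log2 difference 0.58, SE 0.09), from 20.7 ± 2.19 in control sham medulla to 37 ± 7.04 in KO sham medulla, while its other probe set read 0.08 (adjusted p = 1). Lrp2, the endocytic receptor megalin, rose at a level near background, where no fold is given (log2 difference 0.38, SE 0.06, 6.92 ± 1.45 in control sham medulla and 11.6 ± 3.87 in KO sham medulla), while its other probe set read -0.21 and that of Axin1 -0.12 (both adjusted p = 1). Other probe sets of Iqgap1 read 0.37, 0.20, 0.13 and 0.02, those of Hdgfl3 0.045 and -0.04 and that of Spon1 -0.13, and none passed. In limma's moderated test 12 probe sets of 10 genes passed, 4 higher and 8 lower in KO mice, with 760 probe sets at an unadjusted p under 0.05 against 1131 that chance alone would give. Adjusted p was 9.48e-04 for Pgap2, 0.00213 for Iqgap1, 0.00215 for Dctn5, 0.00699 for Myo7a, 0.0104 for Axin1, 0.0167 for Hdgfl3, 0.0169 for Tlr4, 0.0233 for Spon1 and 0.0311 for Lrp2. For each of these 9 genes, and on the probe sets named here and chosen by their small p, every KO medulla array lay beyond every control medulla array. Folh1, which cleaves the peptide N-acetylaspartylglutamate, read 0.89 (SE 0.17) and did not pass (adjusted p = 0.147), though it did without KO sham 3 (0.0346).

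How firmly these medulla calls stood differed between the genes. Axin1, Iqgap1, Dctn5, Myo7a and Pgap2 passed in each of the 16 fits that left out an array in turn. Tlr4 was lost without KO CCI 2 (adjusted p = 0.0540), control CCI 1 (0.0587), control sham 2 (0.0570), control sham 3 (0.0532) or control sham 4 (0.0517), and with an intensity-dependent robust variance (0.0538). Hdgfl3 was lost without control sham 2 (0.0556) or control sham 4 (0.0517). Spon1 was lost in 12 of 16 omissions (0.0539 to 0.0757, all arrays but KO CCI 1, KO sham 1, KO sham 4 and control sham 2) and with the array code as a block of 3 levels (0.108). Lrp2 was lost in 12 as well (0.0526 to 0.110, all arrays but control sham 1, KO sham 2, KO sham 4 and KO CCI 3). Of the other settings Lrp2 was lost in 8 of 13, among them a pseudocount of 64 (0.13, adjusted p = 0.684) and an intensity-dependent robust variance (0.586), Spon1 in 6 of 14 and Tlr4 in 4 of 14. Without control sham 4 the number of probe sets fell from 12 to 7. Without the animals of low Ttr level in the medulla (control sham 4 and KO CCI 1) it was 6, and Axin1 (0.0621), Myo7a (0.0535), Hdgfl3 (0.104), Tlr4 (0.0631) and Lrp2 (0.264) no longer passed. Within the lower array code no probe set passed and within the higher code 1 did, each with at most 8 of the 16 arrays. Within the lower and the higher code Iqgap1 read 0.92 and 0.95, Dctn5 -1.46 and -0.99, Myo7a -0.93 and -1.09, Axin1 1.15 and 1.38, and Tlr4 0.54 and 0.67. The same direction within both codes was fixed beforehand, since every KO array lay beyond every control array on these probe sets. Over all alternatives the adjusted p ran from 4.92e-04 to 1 for Axin1, from 0.00103 to 1 for Myo7a, from 0.00191 to 0.6 for Hdgfl3, from 0.00679 to 0.886 for Tlr4, from 0.00294 to 0.886 for Spon1, from 0.00624 to 1 for Lrp2 and from 0.00780 to 1 for Folh1. For each of these 7 genes the highest came from a fit within an array code.

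Of the fixed gene lists, 2 of 27 passed for genotype in the medulla. The CCK system, 4 genes for cholecystokinin, gastrin and their receptors, was lower in KO mice (adjusted p = 7.98e-04, and adjusted p = 0.271 with an estimated correlation). Its median log2 difference of -0.03 and its mean of -0.68 show that Cckbr alone carried it: Cck read -0.01, Cckar -0.05 and Gast -0.02, and 1 gene passed both over all genes tested and adjusted over the list alone. Heat shock and unfolded protein genes were slightly higher as a list (adjusted p = 0.0475, and adjusted p = 0.737 with an estimated correlation). Of these chaperone genes, 20 of 28 were higher with a median of 0.03, including the endoplasmic reticulum chaperones Pdia6 at 0.26 and Hspa5 at 0.20, and none passed over all genes or adjusted over the list alone. That call was lost in 9 of 16 omissions (0.0743 to 0.286, all arrays but control sham 1, control sham 3, KO sham 2, KO sham 3, control CCI 1, control CCI 3 and KO CCI 3), with the title number as a block (0.0594) and without the animals of low Ttr level (0.139). Toll-like receptor and innate signalling genes did not pass as a list (adjusted p = 0.529), and adjusted over the list alone 1 gene, Tlr4, was higher. Tlr4 and this list were chosen because published work on these mice names the receptor, so they are not independent evidence of a direction. The median of that list was negative, while its mean and its test were positive. Adjusted over the list alone, 1 gene each was lower in the oxidative phosphorylation and circadian clock lists, neither of which passed. The lists other than these 2 calls lay at adjusted p from 0.0712 to 0.948.

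Genes next to Cckbr were tested as a group, because a targeted allele carries its chromosomal surroundings with it. Among the 50 measured genes on each side, Pgap2 was the 1 of 100 that passed in medulla, against 8 of 12268 other genes (Fisher exact p = 0.0705, with both tails). Trim30a read -0.70 (adjusted p = 0.0714), Trim12a -0.57 (0.0953), Trim34a -0.91 (0.122) and Cavin3 -0.28 (0.215), none of which passed. At an unadjusted p under 0.05 on any of their probe sets stood 14% of the neighbours and 5.05% of the other genes (Fisher exact p = 5.56e-04). With 100 genes on each side 4 of 200 passed, against 5 of 12168 (Fisher exact p = 7.85e-06), and with 25 on each side 1 of 50 (0.0358). In midbrain Trim34a and Pgap2 passed, 2 of 100 neighbours against 4 of 12268 other genes (Fisher exact p = 9.51e-04). At an unadjusted p there stood 20% and 11.5% (0.0170). With 100 genes on each side 5 of 200 passed in midbrain, against 1 of 12168 (Fisher exact p = 6.23e-09), and with 25 on each side 2 of 50 (2.38e-04). Counted outward from Cckbr, the share at an unadjusted p was 16% at 1 to 25 genes, 12% at 26 to 50, 26% at 51 to 100, 10% from there to 200 and 4.85% beyond in medulla, and 22%, 18%, 32%, 10.5% and 10.8% in midbrain, so it was not highest next to Cckbr. A segment carried with the allele could span many genes, so this order does not decide on it. For CCI in control medulla 0% of the 100 neighbours and 4.38% of other genes stood at that p, and in KO medulla 6% and 6.66%. In midbrain the shares for CCI were 3% and 4.59% in control mice, and 13% and 12.7% in KO mice.

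**Figure D2:**
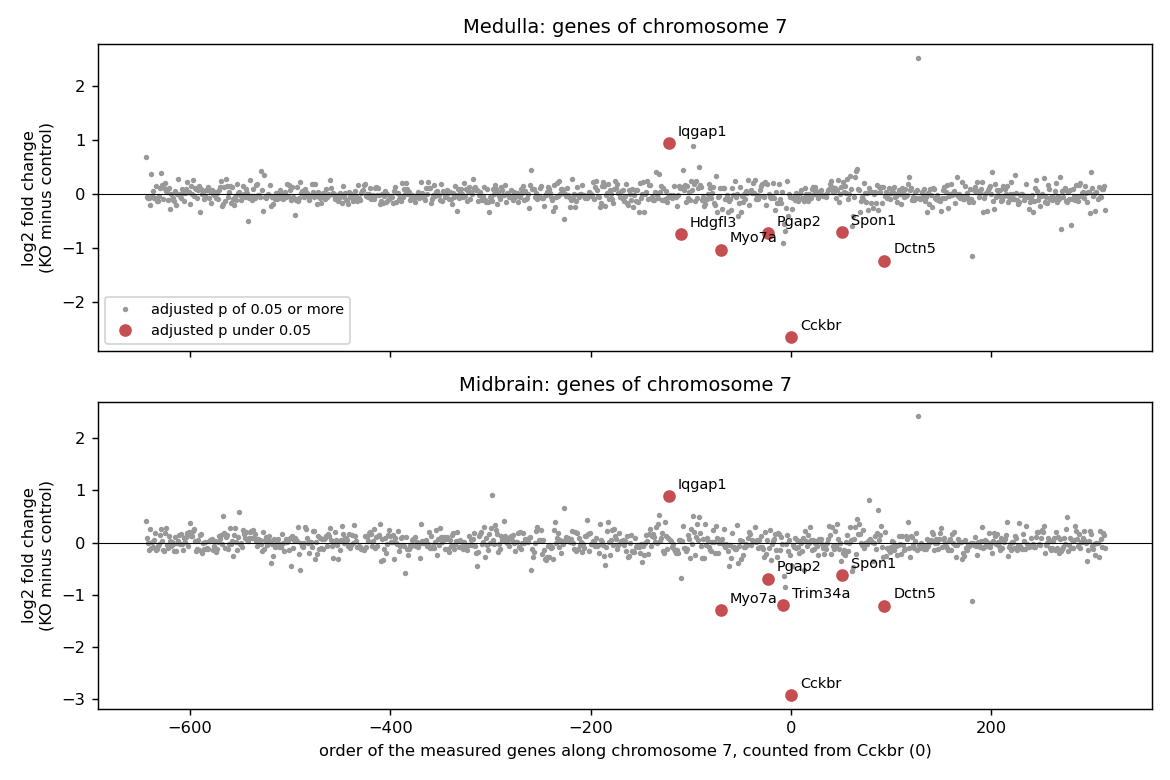
Log2 difference between KO and control mice, averaged over operation, for the measured genes of chromosome 7 in medulla (top) and midbrain (bottom), against their order along the chromosome counted from Cckbr at 0. Each point is 1 gene at its probe set of lowest p, and named red points passed an adjusted p of 0.05.

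Sham mice and CCI mice were also compared separately in the medulla. In sham mice Cckbr fell (-2.56, SE 0.16, adjusted p = 1.75e-06), Pgap2 fell (-0.85) and Iqgap1 rose (1.18), the latter pair at adjusted p = 0.00933. In CCI mice Cckbr fell (-2.76, SE 0.16, adjusted p = 5.76e-07) and was alone in passing. Tlr4 read 0.52 in sham mice (adjusted p = 0.694) and 0.63 in CCI mice (0.367), and neither passed. Dctn5 read -1.27 (0.0889) and -1.21 (0.318), and Axin1 1.35 in sham mice (0.192). In sham mice Axin1 passed without KO sham 4 (0.0370), and Dctn5 in 3 of 16 other settings (lowest 0.0247). The counts were 3 probe sets in sham mice (863 at an unadjusted p under 0.05) and 1 in CCI mice (551). A difference between the operations is the interaction, given with the effects of CCI. Iqgap1 in sham mice was lost without control sham 1 (0.0664), control sham 2 (0.0658), control sham 4 (0.0585) or KO sham 3 (0.0791), and Pgap2 without control sham 1 (0.0664), control sham 3 (0.0553) or control sham 4 (0.0585). The sham count was 1 without control sham 1 or control sham 4, 5 without KO sham 1 or KO sham 2 and 6 without KO sham 4. The CCI count was 2 without control CCI 3, when Trim12a passed (0.00526). Within array codes Cckbr read -2.63 and -2.42 in sham mice (adjusted p = 0.444 and 0.403) and -2.92 and -2.61 in CCI mice (0.134 and 0.196), for the lower and the higher code. With the array code as a block of 3 levels Pgap2 (0.0895) and Iqgap1 (0.0767) in sham mice were lost.

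In the midbrain, which holds the periaqueductal grey and the dopaminergic nuclei, the same averaged comparison was made. Apart from Cckbr, 6 genes passed. Myo7a fell 2.45-fold (SE of log2 0.13), from 77.1 ± 5.97 in control sham midbrain to 21.6 ± 7.27 in KO sham midbrain (SD, n = 4). Dctn5 fell 2.30-fold (SE of log2 0.16), from 703 ± 44.1 to 294 ± 96.9 in the same groups. Trim34a, an interferon-inducible tripartite-motif gene, fell from 35.1 ± 5.99 to 8.32 ± 12.6 (log2 difference -1.19, SE 0.16), with no fold given because the KO level is near background, and its other probe set read 0.27 without passing. Pgap2 fell 1.61-fold and Spon1 1.53-fold, and Iqgap1 rose 1.84-fold (SE of log2 0.11), from 88.5 ± 8.78 in control sham midbrain to 208 ± 38.2 in KO sham midbrain. Other probe sets of Iqgap1 read 0.42 (SE 0.09, adjusted p = 0.168), 0.19, 0.11 and -0.10, those of Pgap2 -0.39 and -0.32 and that of Spon1 -0.14, and none passed. Tlr4 read 15.0 ± 3.01 in control sham midbrain and 15.3 ± 5.62 in control CCI midbrain, against 44.6 ± 20.4 in KO sham midbrain and 46.2 ± 1.82 in KO CCI midbrain, a difference of 0.91 (SE 0.15) that did not pass (adjusted p = 0.0637). Its other probe set read -0.05 (adjusted p = 0.937). In limma's test 7 probe sets passed, 1 higher and 6 lower, with 1694 at an unadjusted p under 0.05 against 1131 by chance. Adjusted p was 5.07e-04 for Myo7a, 0.00780 for Iqgap1, 0.0110 for Dctn5, Trim34a and Spon1, and 0.0290 for Pgap2. Myo15, an unconventional myosin, read 0.39 (0.0648), the replication helicase subunit Mcm7 0.62 (0.0731) and the retinoic acid hydroxylase Cyp26a1 0.46 (0.0950), none of which passed.

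A few arrays weighed heavily on the midbrain result. KO sham midbrain 2 and KO sham midbrain 4 stood apart on the first principal component, at -36 and -26.4. KO sham midbrain 1 and 3 lay at its other end, at 20.1 and 21.9, the highest of the midbrain arrays. KO sham midbrain 2 had an Actb 3' to 5' log2 ratio of 1.602 against at most 0.775 on the other arrays. Without KO sham midbrain 4 the count rose from 7 to 17, and Tlr4 (adjusted p = 8.07e-05) and Mcm7 (0.0219) passed. For Tlr4 this array read 4.998 on the log2 scale, near the control level, against 6.025 to 6.175 in the rest of its group. Its omission therefore removes a KO array without a rise in Tlr4, and its Actb ratio of 0.627 lay within the range of the others. Without both KO sham midbrain 2 and 4 the count rose to 65 probe sets, 34 higher and 31 lower, with Tlr4 at 3.42e-04. Of KO sham midbrain that fit keeps only arrays 1 and 3, both at the positive end of the component. The higher count therefore cannot separate genotype from position on this component. Myo15 passed without KO CCI 1 (0.00865). Pgap2 was lost in 10 of 16 omissions (0.0501 to 0.105, all arrays but KO CCI 1, control CCI 1, KO sham 2, KO sham 3, KO sham 4 and control sham 4) and with the array code as a block of 3 levels (0.0564) or the title number as a block (0.0703). Without the animals of low Ttr level Iqgap1 (0.0535) and Trim34a (0.0726) were lost, and with a pseudocount of 1 Trim34a (0.256) and Pgap2 (0.0683). Tlr4 also passed in 7 other settings, among them an array code block of 2 levels (0.0153), array weights (0.00465) and a title number block (0.0344). Within the lower array code no probe set passed and within the higher code 1 did. Myo7a read -1.12 and -1.41 within the codes, Dctn5 -1.42 and -0.94, Iqgap1 0.95 and 0.76, and Tlr4 0.94 (adjusted p = 0.622) and 0.89 (0.880). Over all alternatives the adjusted p ran from 8.07e-05 to 0.880 for Tlr4, from 0.0113 to 0.912 for Mcm7, from 0.00865 to 1 for Myo15, from 9.75e-04 to 1 for Iqgap1, from 2.93e-05 to 1 for Trim34a and from 0.00478 to 1 for Pgap2.

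Among the lists 2 of 27 passed for genotype in the midbrain. Circadian clock genes were lower in KO mice (adjusted p = 0.0119, and adjusted p = 0.167 with an estimated correlation), with 5 of 19 members higher. Their examples were the clock output factor Dbp at -0.31 and the nuclear receptors Nr1d1 at -0.16 and Nr1d2 at -0.14, and none passed over all genes or adjusted over the list alone. Toll-like receptor and innate signalling genes were higher (adjusted p = 0.0291, and adjusted p = 0.167 with an estimated correlation), with 22 of 32 members higher. Adjusted over the list alone 2 passed, Tlr4 and its co-receptor Cd14 (0.66), and over all genes none did. The accessory protein Ly96 read -0.25 and the transcription factor Irf3 0.19. This list is not independent evidence either, for the reason given with the medulla. The circadian call was lost without KO CCI 4 (0.0501) or control sham 3 (0.0538), and the Toll-like receptor call without KO sham 2 (0.114), KO CCI 4 (0.119), control CCI 3 (0.0642) or control sham 3 (0.0681), or without the arrays that stood apart (0.0921). The CCK system did not pass (adjusted p = 0.0967), though it was the 1 list that did with fry (1.42e-07): its test and its mean of -0.67 were negative and its median of 0.02 positive, with Cck at 0.15 and Cckar at -0.12. Adjusted over the list alone 1 endothelial marker was lower, in a list that did not pass, and the lists without a call lay at 0.0967 to 0.962.

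Within sham and CCI mice the midbrain gave fewer calls. In sham mice Cckbr fell (-2.81, SE 0.15, adjusted p = 3.86e-07), Myo7a fell (-1.32, adjusted p = 0.0296) and Iqgap1 rose (1.10, adjusted p = 0.0347). In CCI mice Cckbr fell (-3.01, SE 0.15, adjusted p = 1.48e-07) and so did Myo7a (-1.27, adjusted p = 0.0453). Spon1 read -0.75 in CCI mice (0.0864), and Tlr4 0.90 in sham mice (0.371) and 0.93 in CCI mice (0.669), none of which passed. The counts were 3 in sham mice (1917 at an unadjusted p under 0.05) and 2 in CCI mice (1123). Myo7a in sham mice passed in 1 of 8 omissions, that of KO sham 2, and Iqgap1 in 1 of 8, that of KO sham 3 (otherwise 0.0669 to 0.139 and 0.0816 to 0.156). Myo7a in CCI mice passed only without control CCI 1 (otherwise 0.103 to 0.294). The sham count was 1 without control sham 1, control sham 2, control sham 4 or KO sham 1, and the CCI count was 1 without any array of its 8 but control CCI 1. With a pseudocount of 1 no probe set passed in either, and Cckbr stood at 0.0851 and 0.120. Within the lower and the higher array code Cckbr read -3.10 and -2.58 in sham mice (0.973 and 0.0532), and -2.92 and -3.11 in CCI mice (0.533 and 0.0175, the latter past the threshold). With the array code as a block of 3 levels Myo7a and Iqgap1 in sham mice were lost (both 0.243), and Myo7a in CCI mice was lost with 3 levels (0.199) and with 2 (0.104).

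Injury in control mice asks which medullary genes respond to a lasting nerve lesion. No gene passed, and the differences of smallest p were in Chrng, a subunit of the muscle acetylcholine receptor (0.83, SE 0.20), the axon guidance gene Sema6a (0.65), and Ciita, the master regulator of MHC class II (0.60). In the other direction stood Fcrla (-0.93), the eosinophil granule gene Prg2 (-0.74) and the muscle myosin Myh1 (-1.11). Cckbr read 0.12, Cck 0.00 and Tlr4 -0.23. Limma called 0 probe sets (smallest adjusted p 1), with 633 at an unadjusted p under 0.05 against 1131 by chance. Choroid plexus markers were higher as a list (adjusted p = 1.64e-09, and adjusted p = 0.587 with an estimated correlation). All 14 were higher with a median of 0.89, among them the water channel Aqp1 at 0.87, the metalloreductase Steap1 at 0.96 and the bicarbonate transporter Slc4a5 at 0.56, and none passed alone, also when adjusted over the list alone. The mean log2 level of the list was 6.75 ± 0.87 in control sham medulla and 7.60 ± 0.66 in control CCI medulla (SD, n = 4), so the difference was about as large as the spread between animals.

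Another 4 lists were lower in the medulla of injured control mice, with no gene passing over all genes or adjusted over the list alone. They were meningeal and fibroblast genes (adjusted p = 0.0236, and adjusted p = 0.997 with an estimated correlation), glucocorticoid and stress response genes (0.0323, and adjusted p = 0.587 with an estimated correlation), red blood cell and granulocyte genes (0.0383, and adjusted p = 0.587 with an estimated correlation) and microglia and macrophage markers (0.0383, and adjusted p = 0.997 with an estimated correlation). Examples were prostaglandin D synthase Ptgds at -0.16, the stress kinase Sgk1 at -0.36, the haemoglobin gene Hba-a1 at -0.36, the Fc receptor Fcgr3 at -0.34 and the complement gene C1qa at -0.21. Among 8 omissions the meningeal call survived those of control CCI 1, control CCI 2 and control sham 4 (otherwise 0.0561 to 0.708), the microglial call the same 3 (otherwise 0.149 to 0.723), the glucocorticoid call those of control sham 1, control sham 2 and control CCI 4 (otherwise 0.0697 to 0.241) and the red blood cell call those of control sham 2 and control CCI 3 (otherwise 0.0508 to 0.331). With the array code as a block the microglial (0.216) and red blood cell (0.324) calls were lost, and the meningeal (0.0206) and glucocorticoid (0.00120) calls stood. The choroid plexus call stood in all 8, and its adjusted p was 3.18e-08 with the array code as a block and from 1.56e-14 to 0.840 over all alternatives. The other 22 lists lay at adjusted p from 0.208 to 0.994.

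Injury in KO mice showed no gene past the threshold in the medulla. The smallest p belonged to Dmp1, a matrix protein of bone and dentine (0.70, SE 0.10, adjusted p = 0.0893), which passed at 0.0419 with 1 probe set per gene. Next came the urea cycle enzyme Cps1 (0.75), the homeobox gene Hlx (0.55), the acute phase gene Orm2 (-1.08), the spindle checkpoint gene Bub3 (-0.63) and the tryptophan hydroxylase Tph1 (-0.65), at adjusted p = 0.993. Limma called 0 probe sets, with 959 at an unadjusted p under 0.05. The count was 1 without KO sham 1, when Nepro passed (4.48e-04), and 1 without KO sham 2. Interferon response genes were lower as a list (adjusted p = 0.0206, and adjusted p = 0.658 with an estimated correlation), with 4 of 24 members higher and a median of -0.10, among them Tap1 at -0.33 and Iigp1 at -0.28. Choroid plexus markers were lower (adjusted p = 0.0206, and adjusted p = 0.918 with an estimated correlation), with 0 of 14 higher, Ttr, the thyroid hormone carrier, at -0.61 and Col8a1 at -0.38. In neither list did a gene pass, also when adjusted over the list alone. The interferon call was lost without KO CCI 1 (0.0640), KO CCI 4 (0.131), KO sham 2 (0.422) or KO sham 4 (0.0801), and the choroid plexus call without KO CCI 1 (0.848), KO sham 1 (0.426), KO sham 2 (0.0720) or KO sham 4 (0.458). The other lists lay at adjusted p from 0.0513 to 0.939.

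Whether the effect of injury depended on genotype was tested as an interaction. In the medulla the positive terms of smallest p were Cps1 (1.18), Dmp1 (0.655) and Myh1 (1.95, SE 0.43), followed by Prg2 (0.92) and Lcp2 (0.66), and the negative term of smallest p was Bub3 (-0.91). Cckbr read -0.21 and Tlr4 0.11. None passed: limma called 0 probe sets (smallest adjusted p 1), with 604 at an unadjusted p under 0.05, and Cps1 passed without control CCI 3 (0.0383). The count was 1 without that array and 1 without KO sham 1. Choroid plexus markers gave a negative interaction (adjusted p = 6.43e-11, and adjusted p = 0.943 with an estimated correlation), with 0 of 14 positive, a median of -1.36, Steap1 at -1.38 and Calml4 at -1.45, and none past the threshold, also when adjusted over the list alone. The list's mean level was 7.38 ± 0.78 in KO sham medulla and 6.93 ± 0.84 in KO CCI medulla (SD, n = 4). The other 26 lists lay at adjusted p from 0.377 to 0.923.

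**Figure D3:**
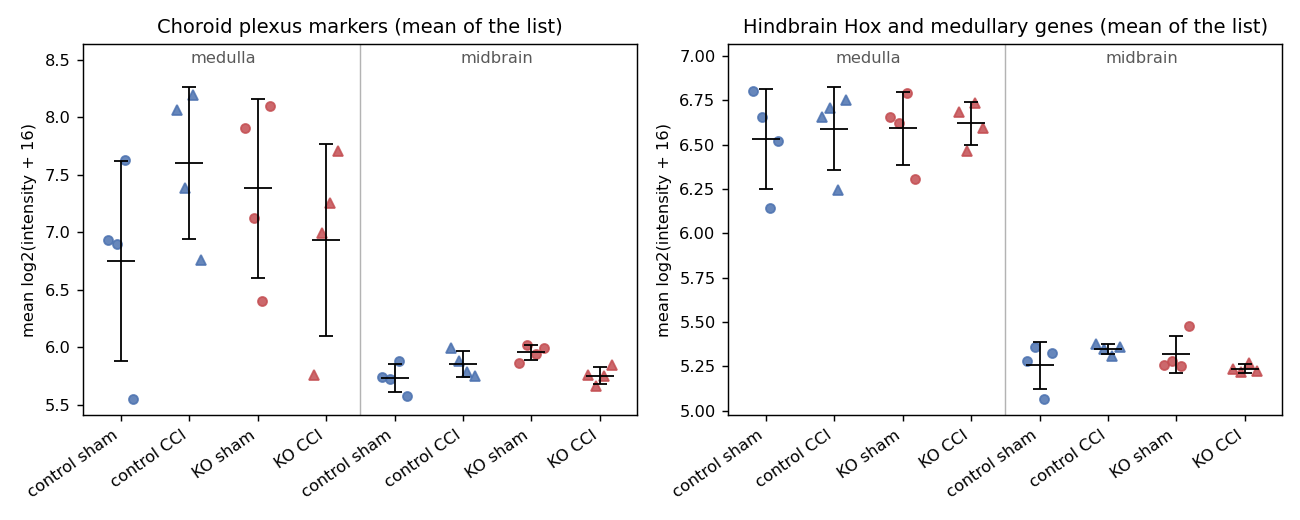
Mean log2(intensity + 16) of the choroid plexus markers (left) and of the hindbrain Hox and medullary genes (right) on each array, in the 8 groups of 4 arrays (circles sham, triangles CCI, blue control, red KO; bar and whiskers, mean ± SD). Choroid plexus levels vary widely between medulla arrays of a group, and all medulla arrays lie above all midbrain arrays in the Hox list.

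In the midbrain injury changed no gene that passed, in either genotype. In control mice the higher genes of smallest p were Trim47 (0.66), the signalosome subunit Cops5 (0.62), Herc2 (0.37), the lysosomal sialidase Neu1 (0.46) and Actn1 (0.29), and the lower genes the cochlear gene Otor (-0.58), Klra16 (-0.47), Stc1 (-0.49) and the butyrophilin Btn1a1 (-0.67), all at adjusted p = 1, and limma called 0 probe sets with 679 at an unadjusted p under 0.05. In KO mice Topors, a ubiquitin and SUMO ligase, read 0.88 (SE 0.15), Rmdn1 0.47 and Pkhd1l1 -0.61, all at adjusted p = 0.601, and limma called 0 with 1863 at an unadjusted p under 0.05 against 1131 by chance. Cckbr read 0.11 in control and -0.08 in KO mice, and Tlr4 0.05 and 0.08. For the interaction limma called 0 probe sets, with 1241 at an unadjusted p under 0.05. Rab27a, a regulator of vesicle secretion, read 0.91, the calcineurin regulator Rcan3 0.94, Cops5 -0.86 and the kinesin adaptor Kifap3 -0.48, at adjusted p = 0.822. Without the arrays that stood apart, the counts were 2 in KO mice and 1 for the interaction.

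Midbrain lists moved little with injury. In control mice meningeal and fibroblast genes were higher (adjusted p = 0.0275, and adjusted p = 0.893 with an estimated correlation), with 17 of 20 members higher, among them the proteoglycans Dcn at 0.34 (SE 0.20) and Bgn at 0.34 (SE 0.21). That call was lost without control sham 2 (0.617), control sham 3 (0.0563), control CCI 3 (0.671) or control CCI 4 (0.0838). The other lists lay at 0.323 to 0.994, and adjusted over the list alone 1 gene passed, a glutamate receptor or transporter gene that was higher. In KO mice no list passed: interferon response and GABA and glycine transmission stood at 0.0624, and the others at 0.0767 to 0.995. The count of lists there was 2 without KO CCI 2 and 1 without KO sham 1. For the interaction, GABA and glycine transmission genes were higher as a list (adjusted p = 0.0477, and adjusted p = 0.143 with an estimated correlation), with 15 of 20 positive and a median of 0.11. Its receptor subunits Gabra3 at 0.66 (SE 0.25), Glra1 at 0.63 (SE 0.27) and Gabbr1 at 0.19 (SE 0.09) did not pass, and no member passed when adjusted over the list alone. That call was lost in 12 of 16 omissions (0.0567 to 0.154, all arrays but control sham 1, control sham 4, KO CCI 2 and control CCI 4) and without the arrays that stood apart (0.180). The other 26 lists lay at adjusted p from 0.240 to 0.981.

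The regions were compared over all 32 arrays, without the animal as a block, as a measure of what the arrays resolve. Dopamine neuron genes marked the midbrain: the dopamine transporter Slc6a3 rose from 2.22 ± 6.76 in KO sham medulla to 587 ± 76.8 in KO sham midbrain (SD, n = 4), a log2 difference of 4.75 over all groups (SE 0.09, adjusted p = 3.61e-24). Th, which makes the dopamine precursor, was higher by 1.94, Ddc by 1.42 and the serotonin transporter Slc6a4 by 1.07. Transcription factors and synaptic genes of the midbrain were higher too, with Tcf7l2 at 3.22, Lhx9 at 2.33, Foxa1 at 1.82, Lhx2 at 1.61 and the postsynaptic protein Nrgn at 2.43, as was the neuropeptide Cartpt at 2.20. The medulla held higher levels of Hox genes, which pattern the hindbrain, with Hoxb5 at -4.11 (SE 0.18), Hoxa5 at -4.07, Hoxc4 at -2.72, Hoxb2 at -2.57 and Hoxa3 at -2.52, and of the choroid plexus genes Ttr (-3.16, SE 0.35), Kcne2 (-2.38) and F5 (-2.21). Cck, the ligand of the missing receptor, was higher in midbrain (0.80, SE 0.08, adjusted p = 6.34e-09) and so was the A receptor Cckar (0.24, adjusted p = 0.0219), while Cckbr read -0.13 (0.276) and Tlr4 0.08 (0.610). In limma's test 4857 probe sets passed, 2376 higher in midbrain and 2481 higher in medulla, and 7151 stood at an unadjusted p under 0.05. They covered 3468 genes, of which 1712 had a probe set higher in midbrain, 1778 a probe set lower there and 22 both.

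Of the lists 12 passed between the regions, of which 5 held with an estimated correlation. The 5 were hindbrain Hox and medullary genes (adjusted p = 1.40e-19, and adjusted p = 4.83e-04 with an estimated correlation; 1 of 23 higher by sign, median -0.93, 16 passing lower, as when adjusted over the list alone), oligodendrocyte and myelin genes (3.42e-13, and adjusted p = 4.83e-04 with an estimated correlation; 1 of 20 higher by sign, median -0.27, 17 passing lower, 18 adjusted over the list alone), midbrain-patterning genes (8.09e-10, and adjusted p = 6.36e-04 with an estimated correlation; 18 of 22 higher by sign, 14 passing higher and 2 lower, 16 and 3 adjusted over the list alone), synaptic plasticity kinases and scaffolds (4.81e-04, and adjusted p = 0.0443 with an estimated correlation; 23 of 28 higher by sign, 11 passing higher and 2 lower, 12 and 2 adjusted over the list alone) and monoaminergic neuron genes (0.00367, and adjusted p = 0.0122 with an estimated correlation; 11 of 19 higher by sign, 7 passing higher and 3 lower, as when adjusted over the list alone). Myelin examples were the connexin Gjb1 at -0.66, the myelin-associated glycoprotein Mag at -0.43 and Ugt8a, which makes galactosylceramide, at -0.45, and synaptic examples the kinase subunit Camk2b at 0.40 and the scaffold Dlg3 at 0.39.

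The other 7 region lists lost their call with an estimated correlation. Choroid plexus markers were lower in midbrain (adjusted p = 6.82e-10, and adjusted p = 0.105 with an estimated correlation; 1 of 14 higher by sign, 12 passing lower and 1 higher, 13 and 1 adjusted over the list alone). Oxidative phosphorylation genes were lower (1.96e-07, and adjusted p = 0.0738 with an estimated correlation; 9 of 80 higher by sign, 25 passing lower and 1 higher, 30 and 1 adjusted over the list alone), with the synthase gene Atp5g1 at -0.28. Cytosolic ribosomal proteins were higher (1.92e-04, and adjusted p = 0.105 with an estimated correlation; 42 of 47 higher by sign, 12 passing higher and 1 lower, 16 and 1 adjusted over the list alone), with Rps19 at 0.17. Circadian clock genes were higher (1.92e-04, and adjusted p = 0.0632 with an estimated correlation; 16 of 19 higher by sign, 11 passing higher and 1 lower, as when adjusted over the list alone), with Tef at 0.32 and Hlf at 0.40. Endothelial markers were lower (0.00367, and adjusted p = 0.105 with an estimated correlation; 5 of 20 higher by sign, 7 passing lower, 9 adjusted over the list alone), with the organic anion transporter Slco1c1 at -0.49. Glutamate receptors and transporters were higher (0.0107, and adjusted p = 0.0754 with an estimated correlation; 9 of 17 higher by sign, 9 passing higher and 1 lower, as when adjusted over the list alone), with the AMPA receptor subunits Gria2 at 0.70 and Gria1 at 0.66, and this call was lost with the animal as a block (0.0552). Meningeal and fibroblast genes were higher (0.0476, and adjusted p = 0.520 with an estimated correlation; 16 of 20 higher by sign, 7 passing higher and 3 lower, 8 and 3 adjusted over the list alone), with Slc22a6 at 0.66 and Serpinf1 at -0.54, and this call was lost with the animal as a block (0.0934), without the arrays that stood apart (0.160) and without the animals of low Ttr level (0.163).

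Another 15 lists did not pass between the regions. Their adjusted p was 0.113 for astrocyte markers, 0.172 for the CCK system, 0.232 for immediate early genes, 0.35 for GABA and glycine transmission and for nerve injury and regeneration genes, 0.380 for glucocorticoid and stress response genes and 0.477 for Toll-like receptor and innate signalling. It was 0.625 for interferon response, 0.740 for the opioid system, for pan-neuronal genes and for heat shock and unfolded protein genes, 0.847 for ion channels studied in pain, 0.862 for neuropeptides, 0.890 for microglia and macrophage markers and 0.903 for red blood cell and granulocyte genes. In the pan-neuronal, microglial, red blood cell and heat shock lists the median and the mean differed in sign.

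Whether genotype or injury acted differently in the regions was tested over all arrays, in a fit that did not pair the regions of an animal. The genotype difference of Il31ra, a subunit of the interleukin 31 receptor, was larger in midbrain by 0.61 (SE 0.14) and that of the sialic acid lectin Siglecf smaller by 0.52 (SE 0.11), both at adjusted p = 0.945. For Tlr4 the term was 0.33 (adjusted p = 1) and for Cckbr -0.25 (adjusted p = 1). Limma called 0 probe sets, with 859 at an unadjusted p under 0.05 against 1131 by chance. For injury in control mice, Ets1 read -0.75, Mtch2 1.13 and the cystatin Cst7 -1.23, all at adjusted p = 1. Limma called 0, with 407 at an unadjusted p under 0.05.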

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

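Of the tests given here, those on chromosome 7 and on probe variants, on the joint movement of choroid plexus genes, on the animals of low Ttr level, on the arrays of the largest splits and on the arrays that stood apart were chosen after the result was seen, and the splits of the samples, the test of the neighbours of Cckbr, the test for exchanged samples and the test of a response to CCI were set before.

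Within a group of 4 arrays, a value far from the other 3 was found in 9 of 216 groups tested (16 probe sets and 11 lists), where chance gives about 1 in 20, or 10.8. On the log2 scale, Tlr4, on the probe set that passed in medulla, read 4.998 in KO sham midbrain 4 against 6.025 to 6.175 in the other arrays of its group. Cckbr, on its brighter probe set, was at the floor, 4.000, in KO sham midbrain 2 against 4.738 to 4.840. Myo7a read 5.938 in control CCI midbrain 1 against 6.600 to 6.650. Pgap2 read 6.235 in KO CCI medulla 4 against 6.635 to 6.714, and 7.265 in control CCI midbrain 3 against 6.874 to 6.940. Hdgfl3 read 9.115 in KO sham midbrain 1 against 8.773 to 8.826. List means stood apart for glucocorticoid and stress response genes in KO sham midbrain 2 (8.203 against 7.985 to 8.022), for Toll-like receptor and innate signalling in control CCI medulla 3 (6.268 against 6.112 to 6.128) and for GABA and glycine transmission in KO sham medulla 3 (8.378 against at most 8.044). Between genotypes the effect of CCI differed for choroid plexus markers in medulla (interaction, adjusted p = 6.43e-11 by camera) and for GABA and glycine transmission in midbrain (adjusted p = 0.0477 by camera), neither of which held with an estimated correlation.

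Genotype calls lie on chromosome 7 more often than chance gives: of the 10 genes other than Cckbr that passed in either region, 7 lie there (70%), against 957 of 12368 measured genes (7.74%, Fisher exact p = 1.59e-06), and Tlr4, Axin1 and Lrp2 lie elsewhere. A candidate explanation, that segments of the chromosome around Cckbr from the strain of the targeted allele came with it, stays open, because this p restates the observation. The neighbour test set beforehand gave a Fisher exact p of 0.0705 in medulla and 9.51e-04 in midbrain, and with 100 genes on each side 7.85e-06 and 6.23e-09. The share of genes at an unadjusted p under 0.05 was highest at 51 to 100 genes from Cckbr (26% and 32%), not at 1 to 25 (16% and 22%). Farther out on the chromosome it was 10% and 10.5% up to 200 genes, and 4.85% and 10.8% beyond. Of all genes outside the 100 on each side, 4.88% in medulla and 11.3% in midbrain stood at that p. The excess was thus limited to the surroundings of Cckbr, as a carried segment would give. That the share peaked away from Cckbr does not decide on a segment that could span many genes. Sequence variants under the called probe set alone are argued against for 1 gene (Pgap2), of which another probe set passed in medulla (-0.55, adjusted p = 0.00215). For 4 genes (Iqgap1, Spon1, Hdgfl3 and Trim34a) no other probe set passed in the same direction (Spon1 -0.13 against -0.705 in medulla, and Iqgap1 at most 0.37 against 0.94 in medulla and 0.42 against 0.88 in midbrain, there at an unadjusted p of 2.23e-04), so a variant and a change of a transcript form cannot be told apart, and an effect of the missing receptor itself was not tested. The same holds off chromosome 7 for Tlr4, Axin1 and Lrp2, whose other probe sets read 0.08, -0.12 and -0.21 in medulla. Dctn5 and Myo7a had no other probe set, so they could not be checked in this way.

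Choroid plexus markers differed with CCI in the medulla of control mice by camera (adjusted p = 1.64e-09), which did not pass with an estimated correlation (0.587) or fry (0.840), and their residuals moved together with a median correlation of 0.918 over the medulla arrays, against at most 0.291 for 1000 random lists, so a different share of choroid plexus in the dissected tissue is a candidate explanation, with Ttr at 6480 ± 3720 in control sham medulla and 8980 ± 756 in control CCI medulla. Of the 14 list genes 1 is held by another list, and 2 lay above the median gene in midbrain. An exchange of medulla and midbrain samples is argued against, since the lowest Hox score of the low medulla arrays was 6.519, against at most 5.475 in midbrain. Animals of low level stay open as the cause: without both the adjusted p was 2.04e-04 by camera and 0.887 with an estimated correlation, and the median shift was 0.485, against 0.889 with them. A response to CCI stays open too: 7 of the 35 splits of the control medulla arrays gave a shift as large as the real 0.889, with 1.387 the highest other, and the bound set beforehand, 2 or more such splits to exclude it, was wrong, because missing a threshold does not show that values did not differ.

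A few KO sham arrays stood apart from their group, though in midbrain this group split to both ends of the first principal component. KO sham midbrain 2 had an Actb 3' to 5' log2 ratio of 1.602, against 0.364 to 0.775 on the other arrays, so RNA degradation is a candidate explanation for it. For KO sham medulla 3 and KO sham midbrain 4 the ratios of 0.730 and 0.627 lay within the range of the others and give no sign of degradation. The former lies near the top of that range, so this ratio alone does not exclude it. KO sham medulla 3 also had the highest share of values at or below 0, 4.58% against at most 3.17%, as a weak array would. Array numbers place it and KO sham midbrain 4 with the same animal, and their residuals correlated at 0.219. With the other KO sham midbrain arrays the value was at most -0.060, though residuals from a group mean sum to 0, so a high value for 1 pair lowers the others. A difference of that animal stays open too, and what it would be was not tested.

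Other splits of the same arrays were run for every count of probe sets. Chance can be excluded for genotype averaged over operation in medulla (12 probe sets, 1 of 100 splits as large, highest other 2) and midbrain (7, 1 of 100, highest other 6), for genotype in CCI mice in midbrain (2, 1 of 35, highest other 1) and for region (4857, 1 of 100, highest other 1093). Cckbr is missing in KO mice, so its call in the genotype counts was fixed beforehand. Without it the averaged genotype count was 10 in medulla (1 of 100, highest other 2). In midbrain it was 6 (2 of 100, highest other 6), so another split gave as many. In CCI mice in midbrain it was 1 (2 of 35, highest other 1), so there chance could not be excluded beyond the targeted gene. At an unadjusted p under 0.05, 76 of 100 splits gave as many as the 760 of genotype in medulla (highest other 2889) and 13 of 100 as many as the 1694 in midbrain (highest other 3499), so there it could not be excluded. Nor could it for the 1917 of genotype in sham midbrain (11 of 35, highest other 3968) or the 1863 of CCI in KO midbrain (12 of 35, highest other 3252). By the counts past the threshold, chance could not be excluded for genotype in sham mice in medulla (3, 2 of 35, highest other 6) and midbrain (3, 2 of 35, highest other 113) or for genotype in CCI mice in medulla (1, 2 of 35, highest other 1). Every count of 0 was matched by all splits, as it must be, so these test nothing: 35 of 35 for CCI in control medulla (highest other 1), KO medulla (1), control midbrain (2) and KO midbrain (1) and for CCI by region (0), and 100 of 100 for the interaction in medulla (284) and midbrain (1) and for genotype by region (1). Splits that called 284 probe sets for the interaction in medulla and 113 in sham midbrain point to a structure of the samples other than their groups. The split with 284 nearly followed the array code, with all 7 arrays of the lower code on a side and 7 of the 8 of the higher code on the other, and the interaction itself gave 0 with the code as a block. The split with 113 had KO sham midbrain 2 and 4, which stood apart, on the same side, and KO sham midbrain 1 and 3 on the other. Its sides followed the first principal component, at -36 to 0.623 against 6.8 to 21.9, and both held arrays of the lower and the higher code. The cause of either split was not tested.

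For the number of lists called, chance can be excluded for region in the fit without animals as a block (12 lists, 1 of 100 splits as large, highest other 11). The margin is narrow: the count was 11 to 12 over animals left out. With the animal as a block the glutamate and meningeal calls were lost, and splits were not run for that fit. Chance could not be excluded for genotype in medulla (2, 53 of 100, highest other 9) and midbrain (2, 21 of 100, highest other 5). The same holds for CCI in control medulla (5, 10 of 35, highest other 9), KO medulla (2, 17 of 35, highest other 10) and control midbrain (1, 26 of 35, highest other 5), and for the interaction in medulla (1, 81 of 100, highest other 9) and midbrain (1, 53 of 100, highest other 6). For CCI in KO midbrain the count of 0 was matched by 35 of 35 splits (highest other 2), as any count of 0 would be.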

How the results depend on the processing

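Quantile normalization before the floor, the omission of the arrays that stood apart (KO sham medulla 3, KO sham midbrain 2 and 4) and that of the animals of low Ttr level (control sham 4, KO CCI 1) were chosen after seeing the data, and the other alternatives before. Where a result changed, the cause was not tested, except that fits within an array code, with only the groups of a comparison or with arrays left out have fewer samples, and that 1 probe set per gene tests fewer probe sets.

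Cckbr, on its brighter probe set, was lower in KO mice under every alternative run for the genotype comparisons. In 182 results for named genes, median centring left 180 as they were and ended 2 calls, quantile normalization before the floor ended 1, and the pseudocount of 1 ended 9 and reversed 1. A pseudocount of 64 ended 1 call and started 3, a trended robust variance ended 2 and started 3, array weights ended 2 and started 11, leaving out the arrays that stood apart ended 5 and started 6, and leaving out the animals of low Ttr level ended 13 and started 1. In 136 results, fits within the lower code ended 27 calls and reversed 1, and within the higher code ended 24. The reversed values lay near 0: the Tlr4 probe set that passed nowhere, for genotype in midbrain (main value -0.05) read 0.129 within the lower code, with -0.117 to 0.003 over arrays left out, and the dimmer Cckbr probe set for region (main value -0.02) read 0.098 with a pseudocount of 1, with -0.088 to 0.010 over animals left out.

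Cck, Cckar and uncalled Cckbr and Tlr4 values of other comparisons are summarised as counts, a choice made after a first run had shown that they change sign. Of 1596 such values 140 had the opposite sign, in 36 of 63 combinations of probe set and comparison, none of them a called value, and 3 newly passed and 2 no longer passed. Of 2952 values of list members 15 had the opposite sign, none called, and 25 newly passed.

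Counts of probe sets moved by over 1.5 times as follows. For genotype in medulla (12) they were 0 within the lower code, 1 within the higher code, 6 without the animals of low Ttr level, and 7 to 15 over arrays left out. In sham medulla (3) they were 5 with a pseudocount of 64, 5 without the dimmest 33.3% of probe sets, 1 with only the groups compared, 1 with the code block of 3 levels, 0 within the lower code, 0 within the higher code, 1 without the animals of low Ttr level, and 1 to 6 over arrays left out. In CCI medulla (1) they were 7 with array weights, 0 within either code, and 1 to 2 over arrays left out. For genotype in midbrain (7) they were 13 with a pseudocount of 64, 12 without the dimmest 33.3% of probe sets, 16 with the trended robust variance, 15 with array weights, 11 with the code block of 3 or of 2 levels, 0 within the lower code, 1 within the higher code, 11 with the title number as a block, 65 without the arrays that stood apart, and 6 to 17 over arrays left out. In sham midbrain (3) they were 0 with a pseudocount of 1, 1 with only the groups compared, 1 with the code block of 3 levels, 0 within either code, 1 with the title block, 11 without the arrays that stood apart, and 1 to 4 over arrays left out. In CCI midbrain (2) they were 0 with a pseudocount of 1, 5 with array weights, 4 with only the groups compared, 1 with the code block of 3 or of 2 levels, 0 within the lower code, 1 within the higher code, 1 with the title block, 5 without the arrays that stood apart, 1 without the animals of low Ttr level, and 1 to 2 over arrays left out. Counts of 0 became 1 for CCI in KO medulla with 1 probe set per gene, 2 for CCI in KO midbrain, 1 for the interaction in midbrain and 1 for genotype by region without the arrays that stood apart, and 0 to 1 over arrays left out for CCI in KO medulla and the interaction in medulla. For region (4857) the count was 3181 with 1 probe set per gene and 4303 to 5406 over animals left out.

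Counts of lists moved too. With camera and an estimated correlation 5 of 12 region lists held and 0 in every other comparison. With fry the count was 1 for genotype in either region, the CCK system each time (adjusted p = 3.60e-04 in medulla and 1.42e-07 in midbrain), so neither midbrain call by camera held, and 0 for the CCI comparisons and interactions that had calls. Median centring gave 4 for genotype in medulla, 3 for CCI in control medulla and 0 for the interaction in midbrain. The title block gave 1 for genotype and 1 for CCI in KO mice in medulla, and the code block 2 for CCI in control midbrain. Without the arrays that stood apart there were 5 for CCI in KO medulla, 1 for genotype in midbrain and 0 for the interaction there, and without the animals of low Ttr level 1 for CCI in KO medulla, 2 for the interaction in medulla and 0 in midbrain. Over arrays left out the ranges were 1 to 4 for genotype in medulla, 1 to 4 for CCI in control medulla, 0 to 5 for CCI in KO medulla, 1 to 3 for the interaction in medulla, 0 to 3 for genotype in midbrain, 0 to 2 for CCI in control midbrain, for CCI in KO midbrain and for the interaction there, and 11 to 12 for region. For the neighbours of Cckbr in medulla (Fisher exact p = 0.0705) the p was 0.0358 with 25 genes on each side and 7.85e-06 with 100.

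Arrays that share a title number within a region share only a number as far as the labels say. Their residuals correlated at 0.042 in medulla and 0.066 in midbrain. For different numbers the values were -0.014 and -0.022, which follow from the former because residuals from a group mean sum to 0. Some calls of dim genes depended on the pseudocount: Lrp2 in medulla read 0.38 (adjusted p = 0.0311) and 0.13 (0.684) with a pseudocount of 64, and Trim34a in midbrain -1.19 (0.0110) and -2.81 (0.256) with a pseudocount of 1.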

Other observations

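The test of values shared between regions was chosen after the result was seen, as were its limit on the spread and the genes named here, and the test of the array code was set before.

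A set of probe sets varied between animals in the same way in both regions. Of 1691 probe sets with a residual SD of at least 0.3 in both regions, 30 had residuals correlated at 0.9 or more between the regions when arrays were paired by array number, against 16 when paired by title number and at most 4 in 100 random pairings within the animal groups. Without the limit on the spread the count was 120, against at most 28. A candidate explanation is a genotype that the arrays of an animal share at loci that differ between animals. A batch marked by the array code as the whole cause is argued against, since random pairings within the group and the code gave at most 23 (median 6), and 0 of 100 gave as many. Nothing in these data shows which loci differ.

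Prdx2, a peroxiredoxin of red blood cells and neurons, correlated at 0.988 between the regions, and KO CCI 1 lay 2.12 below its group mean in medulla (residual -2.12). Gdpd3, a lysophospholipase D gene on chromosome 7, correlated at 0.968 by array number and at 0.174 by title number. Its genotype difference was 2.52 (SE 0.52, adjusted p = 0.203) in medulla and 2.43 (SE 0.48, adjusted p = 0.138) in midbrain, and neither passed.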
